A study of Homo sapiens with 38 samples.

How the data were processed

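RNA was extracted from cultured cells, and 6 micrograms of total RNA were labelled with biotin and hybridised to Affymetrix human genome arrays, per the labels' protocols. The authors deposited log2 values for 54675 probe sets on 38 arrays, and GCRMA is named in the submitters' processing notes; its version is not given in the sources used here. The base of the logarithm is not stated and was read from the range, -9.42 to 11.2. Every probe set had a median of 0 over the 38 arrays, so the deposited values were centred per probe set over clones and PBMC together. Levels are therefore lost, the direction of differences is kept, and signal over background cannot be judged. The median of each array lay between -0.08 and 0.02. Scan dates and labelling runs are not given in the sources used here.

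Probe sets were named through the platform annotation of 2016, in which 41097 had 1 gene symbol, 1801 several and 11777 were unlisted, 56 of these being control probe sets. Symbols were matched by gene identifier for 41043 probe sets to a RefSeq gene table of assembly GRCh38.p14, which changed 0 names and left 54 unmatched. That table served only for names, chromosomes and gene order. Probe sets of chromosome Y genes and of XIST and TSIX were left out (59), as were those with several symbols. A gene and a gene list of the design are not reported here; the counts of lists include that list.

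The design was fixed before the data were examined. It assumed uncentred values, with a filter at a log2 level over 4 and the probe set with the highest mean for each gene. Neither can be computed from centred values. No filter was used in their place, and each gene was represented by the probe set with the largest variance over the means in the fit, without regard to groups. This choice favours probe sets with a large difference, both against PBMC and between haploid and diploid clones, whose difference adds to the variance. That change was made after the centring was seen and before the tests.

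The 2 arrays of each clone or sample were averaged. Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment) over 7 haploid and 10 diploid clones at an adjusted p under 0.05. KBM7 was compared with PBMC over all 19 means as the mean of the haploid and diploid means minus PBMC, with a further minimum difference of 1 (2-fold). PBMC had only 2 samples and shared the spread of the clones. Clones grew from separate cells of 1 line, so p-values measure the spread between clones of this line. The sample titles give ploidy and clone number but no lineage. A change that clones of 1 ploidy inherited from a shared founder cell could therefore not be told from ploidy. Lists with at least 5 measured members (20 of cell states and 8 of cell type markers) and chromosomes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Single values were compared with two-sided exact permutation tests over 19448 splits. Figures were drawn with matplotlib 3.10.9.

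Named genes followed a fixed rule. For haploid against diploid clones, with few genes passing, these were all passing genes, the 10 smallest p-values, list members past the threshold (up to 3), and BCR, ABL1 and MYC. For PBMC they were the 10 largest differences each way and up to 3 members of each list past the threshold, by size. Genes outside the rule are said to be chosen after their values were seen.

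Neighbouring genes were scanned in windows of 20 genes, moved by 5, over 3586 genes at least 1 higher (log2) in KBM7 than in PBMC, a stand-in for being expressed in KBM7. The deviation of a clone from the median clone was taken, and windows at 0.4 or more in size were kept. The tests were checked on simulated data. For haploid against diploid clones with 19740 genes, changes of 0.5, 1, 2 and 3 (log2) were recovered in 38, 47, 47 and 50 of 50 genes each, with 12 false calls. For KBM7 against PBMC, 197 of 200 genes changed by 2 were recovered with 0 false calls. In both simulations genes varied independently and many changes were present at once, so these recoveries do not give the power of the real comparisons.

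Alternatives covered array scaling, the choice of probe sets, the model for the 2 extractions, blocks, weights, thresholds and leaving out each clone. Whether numbers pair the samples was checked. The extraction difference (first minus second) had a median correlation of -0.00149 over 136 pairs of clones. Of 7 haploid and diploid clones of the same number, 3 had a correlation over 0.1, but 0 correlated best with their own number. Numbers were not taken as pairs.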

Results

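Gene expression was measured in clones of KBM7, a human chronic myeloid leukemia cell line that is near-haploid and can give rise to diploid cells, and in human peripheral blood mononuclear cells (PBMC), a mixture of lymphocytes and monocytes. Each clone had been grown from a single sorted cell, and its ploidy was checked by flow cytometry. There were 7 haploid clones, 10 diploid clones and 2 PBMC samples. Every clone or sample had 2 RNA extractions with an array each, which gave 38 arrays. The arrays of a clone were averaged, so that n counts clones. The deposited values are log2 values set to a median of 0 for each probe set, so they give differences between samples and no expression level, and a gene that is absent everywhere cannot be told from one that is expressed evenly. The number of clones limits the precision.

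The first comparison asked which genes differed with ploidy within the one cell line. Of 19740 genes, 5 were higher and 4 were lower in haploid than in diploid clones at an adjusted p under 0.05. The largest difference was in ABLIM1, an actin-binding LIM domain protein, at -3.07 ± 0.53 (log2, SE; adjusted p = 0.0439), or 11.9% of the diploid level. Its haploid clones spread widely, from -4.68 to -0.04 (SD 1.59, n = 7), against a diploid SD of 0.72 (n = 10). SPOCK2, a secreted proteoglycan, was 4.01-fold higher in haploid clones (2.00 ± 0.25, adjusted p = 0.0074), and all 7 haploid clones lay above every diploid clone. NYNRIN was 3.76-fold higher (1.91 ± 0.28, adjusted p = 0.0156).

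The other 6 genes differed by less than 2-fold. LRRC27 was higher by 0.79 ± 0.11 on the log2 scale, CFD, which encodes complement factor D, by 0.56 ± 0.09, and ENTR1 by 0.31 ± 0.05. The ion channel gene MCOLN2 was lower, at -0.97 ± 0.16, as were TANC1 at -0.49 ± 0.07 and JDP2, a repressor of AP-1 transcription factors, at -0.48 ± 0.08. Besides SPOCK2, haploid and diploid clones did not overlap in NYNRIN, LRRC27, CFD, ENTR1 and TANC1. They overlapped in JDP2, MCOLN2 and ABLIM1. ANKIB1 had the tenth smallest p and did not pass (0.29 ± 0.05, adjusted p = 0.0591), but it passed in 8 of 31 alternative settings. Where a gene had several probe sets, none moved significantly in the opposite direction, but some showed little difference, such as the LRRC27 probe sets at 0.11 and 0.09. SPOCK2 was at 0.83 by its other probe set, and TANC1 at -0.14 and -0.10 by its others. Of 31 alternative settings, ABLIM1 lost its call in 16, CFD in 15, ENTR1 in 14, MCOLN2 in 13 and JDP2 in 11, while SPOCK2 kept it in all.

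The partners of the BCR-ABL1 fusion and MYC, a growth-promoting transcription factor, did not pass the test. BCR differed by 0.17 ± 0.06 (adjusted p = 0.283), ABL1 by 0.03 ± 0.08 (adjusted p = 0.929) and MYC by 0.13 ± 0.07 (adjusted p = 0.484).

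The count of 9 depended on the model and on single clones. It was 77 without diploid clone 6 and 17 without diploid clone 4. It fell to 3 without haploid clone 4, to 4 without haploid clone 2 or diploid clone 2, 5 or 7, and to 5 without haploid clone 6 or 7. With all arrays in the fit and clone as a random block it was 467, and 441 with the extraction number as a replicate block as well. Such fits take a single consensus correlation for all genes, 0.609 in the first fit. That correlation was higher over genes higher in KBM7 than in PBMC, so arrays of a clone may count as too independent there. With the clone number as a block, over clones 1 to 7 of each ploidy, the count was 1. Centring each array on its median gave 11 higher and 7 lower genes, and a further quantile normalisation 81 higher and 30 lower. At an unadjusted p under 0.05 there were 2377 genes, where 987 are expected on average with no differences. Genes that vary together can move such a count far from its average. It was not taken in random splits of the clones, so no conclusion is drawn from the excess.

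**Figure D1:**
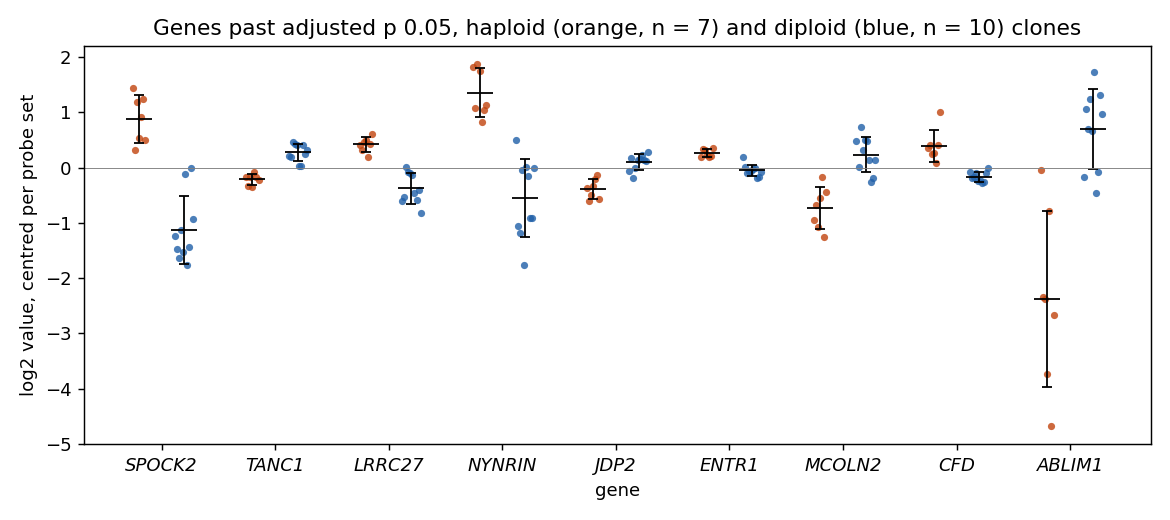
Centred log2 values of the 9 genes past the threshold, 1 point per clone (7 haploid in orange, 10 diploid in blue); black marks are group means and bars 1 SD. Haploid clones lie above diploid ones in SPOCK2, NYNRIN, LRRC27, CFD and ENTR1 and below them in TANC1. The haploid values of ABLIM1 run from -4.68 to -0.04.

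Of 28 gene lists fixed in advance, 6 passed camera with a preset correlation, and no member of any list passed the gene-level threshold. The ATF4 amino acid response had 22 of 24 members negative (median -0.20, adjusted p = 7.7e-05; adjusted p = 0.548 with an estimated correlation). The immediate early genes had 15 of 19 negative (median -0.32, adjusted p = 0.0004; adjusted p = 0.548 with an estimated correlation), and 3 members passed when adjusted over the list alone: CCN1 at -0.46 ± 0.10, ATF3 at -0.65 ± 0.19 and DUSP1 at -0.31 ± 0.10, chosen after their values were seen. In the ATF4 list 0 members passed in this way. T and NK cell markers had 18 of 23 members negative (median -0.04, adjusted p = 0.0273; adjusted p = 0.548 with an estimated correlation), with CD3D at -1.40 ± 0.35 (chosen after its value was seen), and 1 member passed when adjusted over the list alone. That call was lost without haploid clone 2 (adjusted p = 0.0505), haploid clone 4 (0.0856) or diploid clone 4 (0.0977).

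Oxidative phosphorylation had 20 of 25 members positive in haploid minus diploid clones and a median of 0.08 (adjusted p = 0.0008; adjusted p = 0.291 with an estimated correlation). Lysosome genes had 17 of 23 positive and a median of 0.09 (adjusted p = 0.0046; adjusted p = 0.291 with an estimated correlation), with the protease gene CTSA at 0.45 ± 0.09 (also chosen after its value was seen). Adjusted over the list alone, 0 and 2 members passed. No list passed with an estimated correlation. When the 17 clones were split at random into groups of 7 and 10, the median number of lists called was also 6. The fry test, which asks whether a list moves one way, called 4 lists, among them oxidative phosphorylation, lysosome and imprinted genes. Median and mean differed in sign for HLA class II presentation and G1/S and DNA replication, neither of which passed. Proliferation lists did not pass: G2/M and mitosis had 11 members positive and 14 negative (adjusted p = 0.949).

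**Figure D2:**
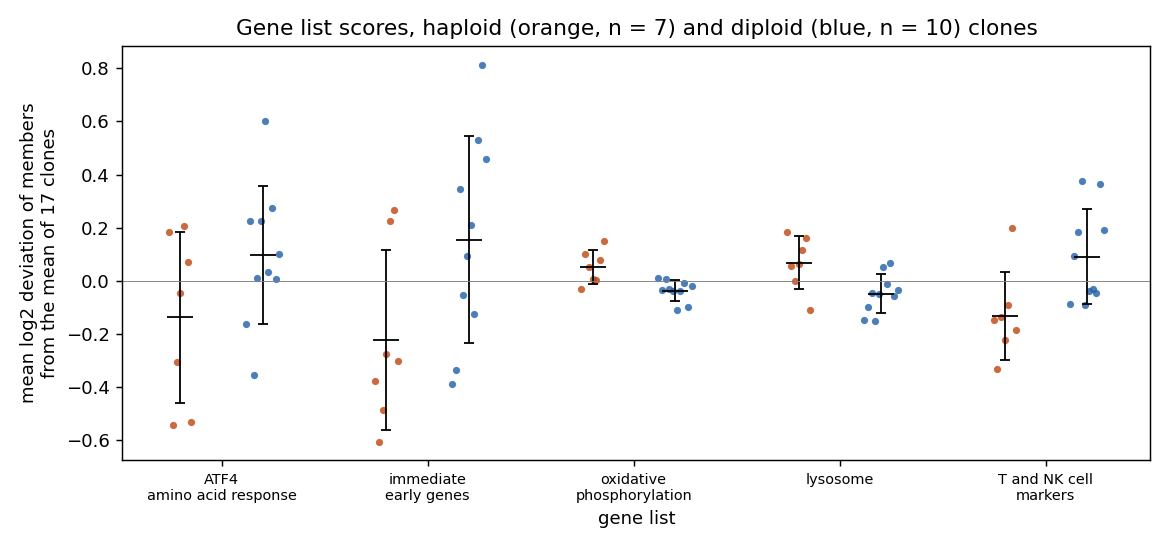
Mean log2 deviation of list members from the mean of the 17 clones, 1 point per clone (7 haploid in orange, 10 diploid in blue), for lists past the threshold with a preset correlation; black marks are group means and bars 1 SD. The haploid mean for oxidative phosphorylation is 0.05 and the diploid mean -0.04, and the groups overlap in each list.

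Control RNAs differed with ploidy as well. The bacterial poly-A control transcripts Dap, Lys, Phe and Thr, which the array's standard protocol adds to the RNA before labelling, were lower in haploid clones by a difference of -0.59 (log2), at -0.46 ± 0.09 (SD, n = 7) against 0.14 ± 0.16 (SD, n = 10; two-sided exact permutation p = 5.1e-05, the smallest the 19448 splits can give; adjusted p = 0.0001 over 14 control measures). No haploid array reached the lowest diploid array. The 18S ribosomal RNA signal was lower by a difference of -0.45 (exact permutation p = 5.1e-05). Controls added at hybridisation differed by -0.08 (exact permutation p = 0.0221, adjusted p = 0.0442), and the Trp control by -0.01 (exact permutation p = 0.475). Trp is not among the transcripts named above as added before labelling, so its small difference does not test labelling. The beta-actin 5' to 3' contrast, a sign of RNA integrity, differed by -0.06 (exact permutation p = 0.408), but lay at -0.54 on the second array of diploid clone 10, against 0.02 on its first, and at -0.49 on the second array of haploid clone 1, against -0.19. This difference divides the clones as ploidy does, so gene and list differences between the groups cannot be assigned to ploidy alone.

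**Figure D3:**
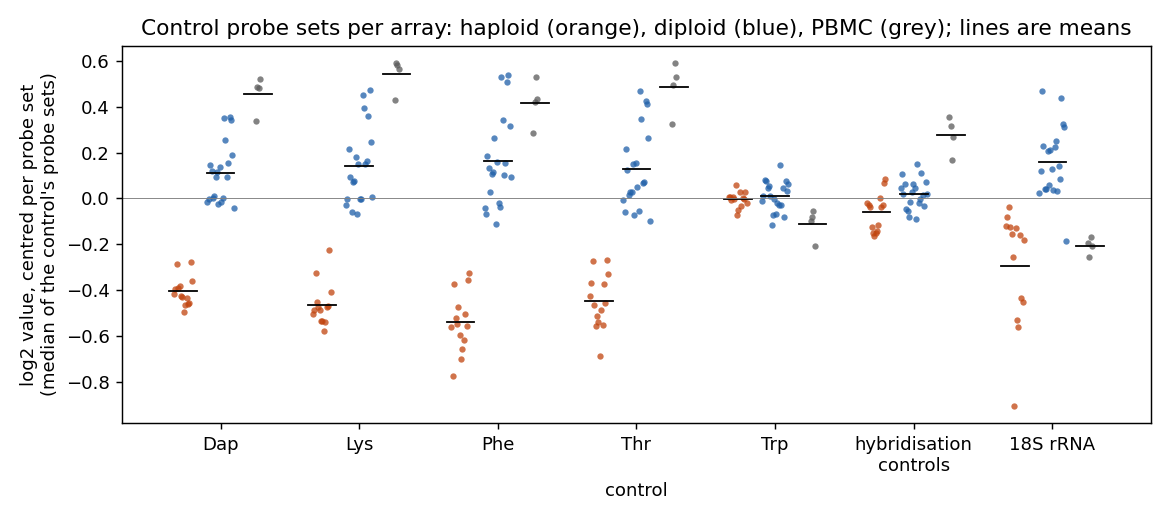
Centred log2 values of control probe sets, 1 point per array (14 haploid in orange, 20 diploid in blue, 4 PBMC in grey); lines are group means. Dap, Lys, Phe and Thr separate haploid from diploid arrays, and Trp and the hybridisation controls overlap.

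Chromosomes were compared because clones of a near-haploid line can gain or lose one. None of 23 chromosomes passed camera (limma; lowest adjusted p = 0.810; 1 at an unadjusted p under 0.05), and the medians per chromosome lay between -0.02 and 0.02. The array scaling removes any shift shared by all genes. Camera compared group means over all genes, so it cannot show a chromosome gained or lost in a single clone. In diploid clone 9 the genes tested on chromosome X had a median deviation of -0.07 from the mean of all clones.

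Along the gene order, single clones had stretches of lower expression. In diploid clone 9, 115 neighbouring genes on chromosome X, from VCF2 to TMLHE, had a median of -0.73 against the median clone, or 60.2% of it, and 91.3% of these genes were lower. Over the same genes the other clones lay between -0.03 and 0.06. The same clone had a median of -0.66 over the first 20 genes scanned on chromosome 18, from TYMSOS to ZNF521. In diploid clone 4, the first 35 genes scanned on chromosome 10, from IDI2 to DEPP1, had a median of -0.69. Diploid clone 6 had 20 genes on chromosome 6 at 0.40. No haploid clone had a window beyond 0.31 in size. The scan and its limit of 0.4 were chosen after the values were seen.

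**Figure D4:**
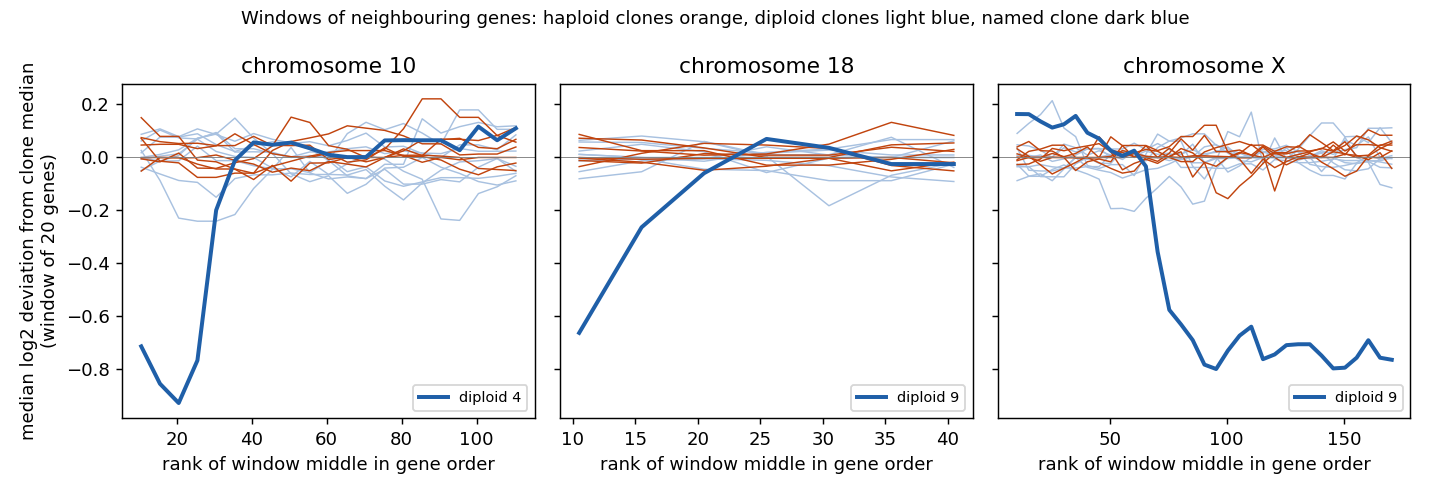
Median log2 deviation from the median clone in windows of 20 neighbouring genes, against the rank of the window's middle in gene order on chromosomes 10, 18 and X; each line is a clone (haploid orange, diploid light blue, the named clone dark blue). Diploid clone 4 drops at the start of chromosome 10, and diploid clone 9 at the start of chromosome 18 and over 115 genes of chromosome X.

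The PBMC samples served as a comparison with normal blood cells. In KBM7 clones 4197 genes were higher and 3386 lower than in PBMC, at an adjusted p under 0.05 and a difference of at least 1 on the log2 scale. Array controls differed in this comparison too. The hybridisation controls had a mean of 0.28 in PBMC, and every PBMC array lay above every clone array. The 5' minus 3' contrast of GAPDH was -0.20 in PBMC against -0.01 in haploid and 0.00 in diploid clones, and that of beta-actin 0.16 against -0.07 and -0.01. The largest decreases were in S100A8, an abundant monocyte and granulocyte protein, at -11.13 ± 0.09 (log2, SE), the fungal receptor gene CLEC7A at -10.43 ± 0.11, the macrophage gene MPEG1 at -10.30 ± 0.09 and the platelet chemokine gene PPBP at -10.19 ± 0.18. UBB, a ubiquitin gene, was at -10.12 ± 0.13. SERPINA1, EREG, GPR183, TRAT1 and CXCR4 followed, between -9.98 and -9.53. The largest increases were in FSTL5 at 8.89 ± 0.12, LIN28B, an RNA-binding protein of early development, at 8.71 ± 0.14, and the homeobox genes SHOX2 at 8.56 ± 0.12 and SIX3 at 8.54 ± 0.08. PNMA2, PPIC, WT1, NFE4, ZIC2 and DSG2 lay between 8.45 and 7.91. The probe set taken for a gene was the most variable one, which favours large differences: B2M was at -3.14 by that probe set and at -0.47 and -0.75 by its others.

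Proliferation genes were higher in KBM7. All 25 G2/M and mitosis genes passed, with a median of 6.06 (adjusted p = 6.2e-17; adjusted p = 0.0264 with an estimated correlation), among them KIF20A at 7.52 and the cyclin gene CCNB1 at 6.98. Of 23 G1/S and DNA replication genes 22 were higher, such as CDC6 at 6.72 (adjusted p = 0.0558 with an estimated correlation), and of 23 centrosome genes 12, such as NEK2 at 7.13 and PLK4 at 4.58 (adjusted p = 0.0193 with an estimated correlation). Metabolic lists were higher with the preset correlation only: ATF4 amino acid response (15 of 24 higher, PSAT1 at 5.80), cholesterol synthesis (11 of 17, SQLE at 3.21), oxidative phosphorylation (8 of 25, UQCRC1 at 2.32) and glycolysis (7 of 18, HK2 at 2.66). Their adjusted p with an estimated correlation was 0.555, 0.342, 0.145 and 0.152. In the cholesterol list, EBP was at 2.03, and another of its probe sets moved the other way at -0.26. The other probe sets of HK2 were at 1.93 and -0.11.

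All 23 T and NK cell markers were lower (median -7.12), including GZMB at -9.49 and CD8A at -9.39, and so were all 15 monocyte markers (median -7.63), 14 of 15 B cell markers (IGHM at -6.73; adjusted p = 0.0903 with an estimated correlation), and 12 of 15 megakaryocyte and platelet markers (PF4 at -8.20). Antigen presentation genes were lower, with 11 of 14 in HLA class I (adjusted p = 0.145 with an estimated correlation) and 10 of 11 in HLA class II (adjusted p = 0.270 with an estimated correlation), where HLA-DQA1 was at -8.53. Adhesion and extracellular matrix genes (22 of 38 lower, THBS1 at -9.42), actin cytoskeleton genes (17 of 34, VIM at -5.08), lysosome genes (13 of 23, CTSS at -3.04; adjusted p = 0.0903 with an estimated correlation) and immediate early genes (13 of 19, FOS at -6.61; adjusted p = 0.270 with an estimated correlation) were lower too. By its other probe set VIM was at -0.64 (limma, adjusted p = 0.0617 over all probe sets). With an estimated correlation the calls for T and NK cell, monocyte, and megakaryocyte and platelet markers, adhesion and actin held. The other 5 calls in this paragraph did not. Adjusted over each list alone, the number of members past the threshold was 25 for G2/M and mitosis, 23 for T and NK cell markers and 15 for monocyte markers. A further quantile normalisation, which forces PBMC and clones to one spread of centred values, left 888 genes.

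**Figure D5:**
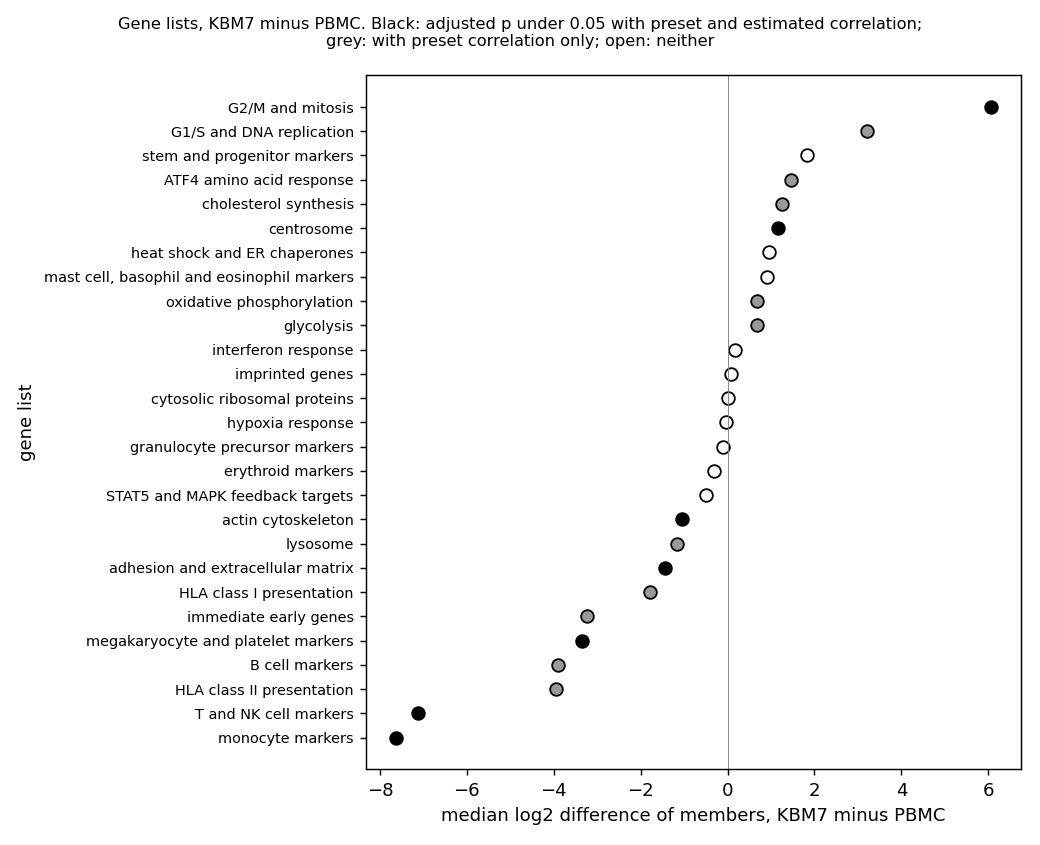
Median log2 difference of list members, KBM7 minus PBMC, for gene lists fixed in advance; black points passed with preset and estimated correlation, grey ones with the preset correlation only and open ones with neither. G2/M and mitosis lies highest, at 6.06, and monocyte markers lowest, at -7.63.

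No difference between haploid and diploid clones in nearness to PBMC was detected by the planned test. The Pearson correlation with the mean PBMC profile was -0.05 ± 0.04 (SD, n = 7) in haploid and -0.07 ± 0.05 (SD, n = 10) in diploid clones (two-sided exact permutation p = 0.464). Since the values are centred over all arrays, 20 of them diploid, this correlation has no absolute meaning, and its group difference depends on that centre. The root mean square difference from PBMC, chosen after seeing the data, does not depend on it. By that measure haploid clones were nearer by 0.006 (two-sided exact permutation p = 0.346). The distance of a clone to the mean of the others of its group was 0.324 ± 0.052 (SD, n = 7) in haploid and 0.330 ± 0.096 (SD, n = 10) in diploid clones (two-sided exact permutation p = 0.894), and diploid clone 6 lay farthest out at 0.559. Haploid clones were set against a mean of fewer clones, which raises their distances slightly. The splits shuffled the finished distances without computing them again, so this test is approximate. The extractions of a clone had a consensus correlation of 0.609, and the SD between them ranged from 0.119 to 0.192 over the 17 clones, highest in diploid clone 10, whose extractions also had the lowest Pearson r, 0.334, against 0.561 to 0.884 in the others.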

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

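The tests of neighbouring genes, hybridisation controls and a separate labelling run were chosen after the result was seen; the splits of the clones and the relations with the poly-A controls were set before.

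Of 82 groups of clone values checked for a single clone far from the others, 3 stood out, where chance gives about 1 in 20, or 4.1. ENTR1 was highest in diploid clone 1 at 0.19, against 0.01 in the next clone. CFD was highest in haploid clone 7 at 1.00, against 0.41 in the next. Diploid clone 6 had the largest distance to the other diploid clones, at 0.559 against 0.382 in the next.

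The 9 genes called between haploid and diploid clones were more than other splits gave. Of 100 splits of the 17 clones, 1, the real one, called as many, and the highest other split called 1 gene. This argues against a chance division of the clones as a source of the count. Only 100 of the 19448 possible splits were drawn, under the reported setting alone, so chance is not excluded. For the gene lists chance is not argued against: 51 of 100 splits called at least 6 lists, and the highest other called 15. For chromosomes the splits decide nothing, since the real count was 0, which all 100 splits reach; the highest other called 1.

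The first pattern is the lower poly-A control signal on haploid arrays. A difference in hybridisation or scanning is argued against, since controls added at hybridisation differed by only -0.0795 where the poly-A controls differed by -0.59. Whether a larger share of mRNA in the total RNA of haploid clones lowers both 18S and poly-A control signals stays open: over the 10 diploid clones the 2 signals had a Pearson r of 0.572 (permutation p = 0.0491, adjusted p = 0.147 over 6 relations) and a Spearman rho of 0.612 (permutation p = 0.0678, adjusted p = 0.203), and r was 0.443 without the 2 farthest clones. The limit set before, an unadjusted p under 0.05, was narrowly met, but the adjusted p was not under it; asking for the adjusted p was decided after the result was seen. Labelling differences would give the same sign. In PBMC the signals went apart, with the poly-A controls at 0.47, above the diploid mean of 0.14, and 18S at -0.21, below the diploid mean of 0.16. A separate labelling run or control dilution for the haploid clones cannot be told apart from ploidy, with a gap of 0.20 between the highest haploid and lowest diploid array and no run in the labels. Within the diploid clones the 9 called genes followed the poly-A level in the direction of their haploid difference with a median r of 0.0663, which 45.1% of random gene sets reached, so whether labelling contributes to those calls stays open.

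The second pattern is the lower expression of neighbouring genes in diploid clones 4 and 9. Chance runs are argued against, since 0 of 100 shuffles of the gene order gave a window as low as the weakest stretch, but the lowest shuffled window, -0.65, came close to the chromosome 18 stretch at -0.66. A single deviating array is argued against as well, because the highest median of any stretch on any array was -0.64. Whether 1 of 2 copies was lost stays open. The stretch median nearest to 0 was -0.66, but windows had been kept for lying at 0.4 or more in size, so a low median is no support. The cut did not fix where the stretches lay. On chromosomes 10 and 18 they began with the first gene scanned, and on X the stretch ran to gene 180 of 181. The remaining genes scanned on chromosomes 10, 18 and X had medians of 0.05, 0.07 and 0.07 in these clones. These values do not tell loss of a copy from regional silencing. Regional silencing without loss was not tested. The 20 genes on chromosome 6 at 0.40 in diploid clone 6 were within what shuffled gene orders gave, up to 0.43.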

How the results depend on the processing

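Alternatives restricted to genes higher in KBM7 than in PBMC, to the more variable genes, without clones 4, 6 and 9, and by root mean square difference were chosen after seeing the data. The planned filter at a level over 6 was not run, since centred values have no level; no filter is the reported setting. Unless said otherwise, the cause was not tested. The 9 genes between haploid and diploid clones became 18 with each array centred, 111 with quantile normalisation again, 27 with the mean of probe sets, 4 with eBayes trend and robust, 4 with the second extraction alone, 467 with all arrays and clone as a random block, 162 with array weights, 3 with a minimum difference of 1, 106 over all probe sets (26 of them controls), 2 among genes higher in KBM7 and 59 without diploid clones 4, 6 and 9. In the paired forms, the replicate block by extraction number gave 441 and the block by clone number 1; 0 of 7 clones correlated best with their own number. Leaving out 1 clone gave 3 to 77. SPOCK2 passed under all 31 of its alternatives, and none of the named genes that passed changed sign; ABLIM1, CFD, ENTR1, MCOLN2 and JDP2 lost their calls in 16, 15, 14, 13 and 11. The 6 lists became 0 with an estimated correlation and 1 among genes higher in KBM7, and 5 to 8 without 1 clone. Against PBMC, 7583 genes became 888 with quantile normalisation and 13262 by adjusted p alone; the replicate block by extraction number gave 7652; leaving out a PBMC sample gave 7344 to 7519, with the lone sample assumed to vary like the clones. The 17 lists became 7 with an estimated correlation. The correlation with PBMC, which depends on the centring, was higher in haploid clones by 0.0491 over genes higher in KBM7 (exact permutation p = 0.0314). In the other settings the exact permutation p ran from 0.115 to 0.464, and by Spearman correlation the sign was opposite, at -0.0488. The consensus correlation of extractions was 0.832 over those genes.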

Other observations

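Of the 28 lists, interferon response genes had the widest spread of clone scores, with an SD of 0.973 over the 17 clones, and the list did not pass between haploid and diploid clones (adjusted p = 0.677; adjusted p = 0.929 with an estimated correlation). The score was 2.13 in diploid clone 3, 1.75 in haploid clone 6 and 1.53 in haploid clone 1, and -1.07 in haploid clones 3 and 4. IFI44L ran from -3.77 to 4.22, the antiviral gene OAS2 from -1.98 to 4.97 and XAF1 from -0.29 to 6.47 (members chosen after their values were seen). Mast cell, basophil and eosinophil markers had a score of 2.64 in diploid clone 6, and HLA class II presentation genes one of -1.91 in haploid clone 6.

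Diploid clone 6 had 248 genes at least 2 (log2) from the median of the other clones on both arrays, against 18 to 141 in the other clones, and in 45 of them no other clone deviated by 1. The largest of these 45, chosen after their values were seen, were ANKRD11 at -6.40, DNAJC12 at 6.23, ATP10A at -6.08 and the cytokine gene LTA at 5.83. In diploid clone 9, EPB41L3 was at -6.20, and the neighbours DPP10 and DPP10-AS1 were at 4.65 and 5.24, also chosen after their values were seen.

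The tests of the interferon pattern were set before their results were seen. An effect confined to 1 of the 2 RNA extractions of a clone is argued against, since the scores of the first and second extraction had a Pearson r of 0.999 over 17 clones (permutation p = 1e-05, the smallest 100000 resamples can give; Spearman rho 0.995, permutation p = 1e-05). An effect of culture or handling shared by both extractions of a clone was not tested. The hypothesis that HLA class I genes may follow the interferon score was not borne out beyond chance: r was 0.216 (permutation p = 0.409, adjusted p = 0.555 over 6 relations), rho 0.110 (permutation p = 0.674, adjusted p = 0.808), and r was 0.250 without the 2 farthest clones.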
